A study of Schizosaccharomyces pombe with 13 samples.

How the data were processed

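RNA was measured by strand-specific sequencing of total RNA from haploid fission yeast (Schizosaccharomyces pombe, ED668 background with the markers ade6-M216, ura4-D18 and leu1-32). The labels list 13 libraries: 4 of wild type and 3 each of a strain lacking xap5 (KanMX4 in its place), a strain lacking pht1 (NatMX4 in its place) and a double deletion strain. Wild type and the xap5 deletion are labelled h+, the pht1 and double deletion h−. Cells were first grown at 30 °C in YES and then at 37 °C in EMM50, and were collected in exponential growth. Ribosomal RNA was depleted, libraries were primed at random, and single reads of 100 bases came from 2 lanes at a stated mean of 11.8 M per library. The labels speak of 3 replicates per genotype and do not say more about how these were grown, so the p-values measure the spread between these libraries, part of which may be technical. No depth of any single library was used here, and no counting interval can be given.

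What the authors deposited is 4 tables of their own comparisons, each deletion strain against wild type, with a log2 fold change, a p-value and an adjusted p-value per feature. Their headers read only logFC, and base 2 is taken from the convention of edgeR, which the submitters' processing notes name together with BWA 0.5.8c, without the role of either or a version of edgeR. The count normalization behind the folds is not given in the sources used here. Annotation is named as Ensembl EF2.12 in a table header. No value per library, mean expression level or standard error was used here, so no test between groups of libraries was run. The deposited p-values of the sense table reach 1.17, with 55 values above 1, and those of the antisense table reach 1.10, with 6 above 1. These values are the authors' own. Why some exceed 1 is not given in the sources used here, and they were left as they are. In the deposited LTR and intergenic tables the adjusted p-values equal Benjamini-Hochberg values over the features of the table.

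The sense table holds 5747 entries, of which 5639 have an identifier in the reference annotation (assembly ASM294v3). Of the 1561 entries of the antisense table, 1052 give signal antisense to an annotated gene, 414 are annotated antisense RNAs with their own level, and 95 are other noncoding RNAs whose 3 folds equal those of the sense table within 0.001. The table appears to list features chosen for a change, by a rule not given in the sources used here: 1530 of its entries have an adjusted p-value under 0.01 in at least 1 comparison, so that its counts may be incomplete, above all at 0.05, and its medians describe chosen features. The adjusted p-values of antisense signal at annotated genes correspond to about 5368 tests, and those of sense entries and annotated antisense RNAs together to about 6413. The LTR table holds 117 long terminal repeats, 114 of them at exactly the position of an LTR in the reference, and the intergenic table holds 6121 regions with a median length of 105 bases. Intergenic starts are printed here 1 base above the deposited start, because that start equals the last base of a gene in 1214 regions. A fold above 20 on the log2 scale in either direction stands for a group without reads and is not printed as a fold. It occurs in 2, 3 and 2 sense entries of the xap5, pht1 and double deletion comparisons.

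Which features count as changed was decided by the deposited adjusted p-value under 0.05, with no test of this work, as fixed before the data were examined for a series with tables of this kind. Also fixed before the data were examined were the 24 gene lists, the rule for named features and the alternatives, apart from those marked in the closing section as added. The double deletion was set against each single deletion by the difference of deposited log2 folds, and the interaction is the double deletion fold minus both single deletion folds. These differences have no error and were not tested. How to count them was settled only after the tables were seen. A feature was counted for them when its adjusted p-value was under 0.05 in at least 1 comparison that enters the difference and the difference was at least 1 on the log2 scale in either direction. For each feature class the median fold and the share above 0 describe the whole class.

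Each gene list was set against all entries of the sense table by a two-sided Fisher exact test of called against uncalled genes, separately for higher and lower, with Benjamini-Hochberg adjustment over the 48 tests of a comparison. The median fold of a list was also placed among 10000 random lists of the same size, which were not matched on expression because no mean expression was used here. Genes within a list are not independent. Counts were made over all genes with the deposited adjusted p-value and again adjusted over the list alone. The lists were mating type M genes, mating type P genes, auxotrophic marker genes, heat shock and chaperones, environmental stress response, meiosis and sporulation, subtelomeric genes, Tf2 retrotransposons, ribosomal proteins, ribosome biogenesis, the wtf family, annotated noncoding RNAs, histones, the SWR1 complex, heterochromatin and RNAi, RNA surveillance, iron uptake and use, phosphate response, thiamine response, galactose and hexose use, nitrogen starvation, MBF cell cycle genes, cell separation genes and mitochondrial genome genes. The rule for the ribosomal protein list, a symbol of rpl, rps or rpp with a number, also takes rpp21, a subunit of RNase MRP. The mitochondrial list took in rps3, here a nuclear gene, beside 3 mitochondrial entries.

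Features were named by rule: both targeted genes, then among features called in a comparison the 10 sense, 6 antisense, 4 LTR and 4 intergenic features that rose most and as many that fell most, the 4 members of each list with the smallest adjusted p-value, and the 5 highest and 5 lowest of each difference. The part of the rule on a minimum expression level or on single libraries could not be applied to these tables. Some features were named outside the rule after their values were seen: SPBC23G7.10c and SPCC1020.13c, the intergenic stretch beside a deleted gene, the genes used in the tests of the closing section, and further list members beyond those 4. The features mat1-Mc, mat3-Mc and SPMTR.04 come in by the rule, but treating them as a set was decided after their values were seen.

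Shared calls of sense entries between comparisons were set beside the number for independent lists, the product of both counts divided by the entries of the table, and beside 200 simulated sets of strains without change that share the same wild type libraries. The 4 wild type libraries could not be split. Features that share reads with a copy were found by sliding windows of 100 bases over the reference. A window recurs when its sequence occurs elsewhere on either strand, and a feature with over 10 percent recurring windows, or one that overlaps another feature of the same strand (for antisense signal, a gene on the strand that carries it), was left out in an alternative. The list test was checked on simulated tables of independent genes, few of them raised and none lowered. It called the planted list in 20 of 20 and none of 800 tests of random lists. Those of the 800 that tested for lower genes could not be called. The check does not give the rate of false calls in these data, where many genes changed. The covariance calculation returned 0.159 for a planted 0.157. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.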

Results

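Transcripts of fission yeast were compared between wild type (4 libraries) and strains that lack xap5, pht1 or both (3 libraries each), all grown at 37 °C. The gene pht1 encodes the histone variant H2A.Z, and xap5 encodes a conserved nuclear protein. The series asks whether both genes restrain aberrant transcripts, and the authors' tables cover 5747 sense entries, 1561 antisense entries, 117 LTRs and 6121 intergenic regions. All folds are the authors' deposited log2 values against wild type, without standard errors, and their base is taken from the convention of the named software. By the labels, the pht1 and double deletions (h−) differ from wild type (h+) in mating type too. Their folds therefore cannot be told apart from mating type. Some mating genes given below did not follow the labels, so the xap5 deletion comparison may hold a mating-type difference as well. The stated mean depth was 11.8 M reads per library, and precision for single features cannot be derived from it.

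The entries of the deleted genes were low in the strains labelled as lacking them, but a stretch inside xap5 was not low in the double deletion. In the authors' deposited table xap5 (SPCC1020.12c, chromosome III 755252 to 756290) fell by 3.11 in the xap5 deletion (adjusted p = 5.84e-14) and by 2.11 in the double deletion (adjusted p = 7.29e-04), and its log2 fold was 0.33 in the pht1 deletion (adjusted p = 0.49). The entry of pht1 (SPBC11B10.10c, chromosome II 1502203 to 1503444) fell by 2.13 in the pht1 deletion (adjusted p = 4.64e-06) and by 1.55 in the double deletion (adjusted p = 1.74e-10), with −0.03 in the xap5 deletion (adjusted p = 0.898). A stretch of the intergenic table inside the reference span of xap5 (III 755406 to 755468) fell by 7.00 in the xap5 deletion, while its deposited fold in the double deletion was −0.09 (adjusted p = 0.964). Whether the double deletion strain carries the same xap5 deletion was left open, and each statement on loss of xap5 in that strain rests on its label and on the lower xap5 entry. Antisense signal rose next to xap5 and at pht1 itself. At SPCC1020.13c, the gene before xap5, it had deposited folds of 4.21, 1.85 and 5.08 in the xap5, pht1 and double deletion. Antisense signal at pht1 had 2.00 in the pht1 deletion and 4.05 in the double deletion.

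Loss of xap5 went with higher stress, chaperone, division and galactose genes and with lower genes of ribosome production. Of the 5747 sense entries, 1213 rose and 1183 fell by the deposited adjusted p-value, and 473 rose and 60 fell by at least 2-fold. The membrane transporter gene mfc1 rose most (log2 fold 6.05, adjusted p = 8.95e-18), followed in the authors' table by the noncoding RNA SPNCRNA.1054 (5.11), SPBPB21E7.10 (4.85), prl43 (4.77), the amino acid transporter gene agp3 (4.73), SPNCRNA.540 (4.51), SPAC4H3.08 (4.32), SPAC11D3.01c (3.87), the enolase gene eno102 (3.86) and ddr48 (3.84). Deposited folds were lowest for SPAC513.04 (−5.56), SPMTR.04 (−5.02), mat3-Mc (−4.28), mat1-Mc (−4.27), SPNCRNA.200 (−4.08), the urea transporter gene SPBC23G7.13c (−3.76), xap5 itself, SPNCRNA.155 (−2.93), the M-factor gene mfm2 (−2.62) and SPNCRNA.389 (−2.42).

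Of 24 genes of the environmental stress response, 22 rose in the xap5 deletion, 1 fell (ssp1, −0.39) and 1 did not pass, with a list median of 1.61 (adjusted p = 1.67e-12 for the list, 23 called adjusted over the list alone). Among them were the small heat shock gene hsp16 (3.70), the catalase gene ctt1 (2.59), tps1 of trehalose synthesis (2.37), the trehalase gene ntp1 (2.29) and the nuclear envelope gene ish1 (2.08) in the deposited table. Chaperone genes rose in 14 of 18 cases with none lower (list median 1.75, adjusted p = 2.25e-06, 14 adjusted over the list alone). They include the Hsp70 gene ssa2 (3.57), sti1 (2.90), the disaggregase gene hsp104 (2.56) and psi1 (2.49). Cells were grown at 37 °C in every group. Genes of cell separation rose in 13 of 17 cases (adjusted p = 7.56e-06, 14 adjusted over the list alone). Authors' folds were 2.33 for the septum glucanase gene eng1, 2.49 for adg2, 1.93 for adg1 and 1.61 for agn1. Genes driven by the MBF factor at the start of S phase rose in 12 of 17 cases and fell in 2 (list median 1.16, adjusted p = 6.93e-05, 15 adjusted over the list alone). Among them were the replication licensing gene cdc18 (1.73), the ribonucleotide reductase gene cdc22 (1.51), mik1 (1.99) and tos4 (1.56). Galactose and hexose genes rose in 8 of 14 cases and fell in 1 (adjusted p = 0.0109, 10 adjusted over the list alone). Deposited folds were 2.80 for ght3, 2.36 for the alpha-galactosidase gene mel1, 2.02 for gal10 and 1.48 for gal1. The wtf family rose in 19 of 25 cases and fell in 2 (list median 0.71, adjusted p = 4.22e-08, 22 adjusted over the list alone). The fold was 1.16 for wtf24, 1.15 for wtf7, 1.06 for wtf18 and 0.88 for wtf9. Without members that share reads or overlap, the list was not called (adjusted p = 0.134). Annotated noncoding RNAs rose in 255 and fell in 18 of 658 cases (adjusted p = 6.13e-27, 272 adjusted over the list alone). Those with the smallest adjusted p-values were SPNCRNA.31 (3.68), SPNCRNA.1278 (2.95), SPNCRNA.867 (2.89) and SPNCRNA.570 (2.38) in the authors' table.

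Ribosome production moved the other way in the xap5 deletion. Ribosome biogenesis genes fell in 32 of 41 cases with none higher (list median −0.47, adjusted p = 6.12e-14, 33 adjusted over the list alone). The deposited table has the helicase genes dbp3 (−1.52) and dbp2 (−1.28), rpf2 (−1.02) and the snoRNP gene nop56 (−0.91) among those that fell. Ribosomal protein genes fell in 70 of 141 cases and 1 rose (list median −0.34, adjusted p = 1.42e-13, 81 adjusted over the list alone). Authors' folds were −0.90 for rpp203, −0.85 for rps1201, −0.72 for rps1202 and −0.62 for rpp21, the RNase MRP gene that the list rule took in. RNA surveillance genes fell in 13 of 25 cases with none higher (list median −0.35, adjusted p = 0.00165, 15 adjusted over the list alone). The gene mmi1, which removes meiotic transcripts, had −0.77, pab2 −0.58, upf1 −0.51 and the RNA helicase gene mtl1 −0.51 in the deposited table.

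Some M-specific mating genes, above all mat1-Mc, mat3-Mc, SPMTR.04 and mfm2, fell in the xap5 deletion although both this strain and wild type are labelled h+, while the pht1 and double deletion strains are labelled h−. Of 8 listed M genes 4 fell and 1 rose (lower, adjusted p = 0.114, 5 adjusted over the list alone). The list median (−0.42) lay at percentile 0.39 among random lists of the same size. The genes mat1-Mc, mat3-Mc and SPMTR.04, which share their sequence, had a median authors' fold of −4.28. Their median was 0.16 in the pht1 deletion and 0.93 in the double deletion. Of 4 P genes map1 (1.28) and map3 (0.53) rose and map2 (0.27) and sxa1 (−0.11) did not pass (adjusted p = 0.307, 2 adjusted over the list alone).

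Apart from the Tf2 elements, given with the LTRs, none of the other lists had a larger share of higher or of lower genes in the xap5 deletion by the list test, although single members changed by the deposited adjusted p-value. Among random lists of the same size, the medians of meiosis and sporulation (percentile 100), thiamine (98.71) and marker genes (1.95) lay near an end. Those of the other lists given below for this strain lay between percentiles 30.78 and 90.67. Meiosis and sporulation genes rose in 40 and fell in 10 of 134 cases (higher, adjusted p = 0.0504, 50 adjusted over the list alone), and fewer fell than among other genes (lower, adjusted p = 1.98e-04), with mug147 at 3.16, mug14 at 2.77, mug191 at 1.64 and mug35 at 1.40. Subtelomeric genes rose in 39 and fell in 18 of 132 cases (higher, adjusted p = 0.0576, 59 adjusted over the list alone), and SPBPB10D8.02c fell by 2.06 in the authors' table. Nitrogen starvation genes went both ways, 5 higher and 7 lower of 15 (lower, adjusted p = 0.0558, 12 adjusted over the list alone). In this list ste11 was at 2.01, isp6 at 1.65, ubi4 at 1.40 and the ammonium transporter gene amt1 at −1.56. Thiamine genes rose in 4 of 7 cases and fell in 1 (adjusted p = 0.0872, 5 adjusted over the list alone), including nmt1 (2.52) and thi2 (1.18). Among histones 4 of 11 rose (adjusted p = 0.378, 4 adjusted over the list alone). Deposited folds were 0.80 for hhf3, 0.70 for htb1, 0.64 for hht3 and 0.49 for hht2. The SWR1 complex, which deposits H2A.Z, had 2 higher and 2 lower of 14 (adjusted p = 0.816, 3 adjusted over the list alone). These include alp5 (−0.46) and arp6 (0.39). Heterochromatin and RNAi genes had 3 higher and 2 lower of 28 (lower, adjusted p = 0.169, 1 adjusted over the list alone), among them swi6 (−0.42) and chp2 (0.36). Iron genes had 6 higher and 2 lower of 20 (adjusted p = 0.528, 8 adjusted over the list alone), including frp2 (1.04). Phosphate genes had 2 higher and 2 lower of 7 (adjusted p = 0.736, 4 adjusted over the list alone), including tgp1 (0.75) and pho1 (−0.63). The marker genes leu1 (−0.74) and ade6 (−0.57) both fell (adjusted p = 0.0872, 2 adjusted over the list alone). Of 4 entries of the mitochondrial list the nuclear gene rps3 alone fell (−0.45; adjusted p = 1 for the list, 1 adjusted over the list alone).

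The pht1 deletion, labelled h− unlike wild type, had higher stress and subtelomeric genes and lower thiamine genes. By the deposited adjusted p-value 775 sense entries rose and 637 fell, of which 236 rose and 30 fell by at least 2-fold. After SPNCRNA.1054 (4.30), the authors' folds were highest for SPCC191.04c (3.58), SPBCPT2R1.10 (3.35), SPAC212.10 (3.29), SPAC186.02c (3.29), SPAC212.09c (3.24), the predicted lactate dehydrogenase gene SPAC186.08c (3.19), SPBCPT2R1.07c (3.10), SPBPB2B2.15 (2.80) and SPAC750.08c (2.71), 8 of which carry identifiers of the subtelomeric list. Of these, SPBCPT2R1.10, SPAC212.10, SPAC212.09c, SPBCPT2R1.07c, SPBPB2B2.15 and SPAC750.08c have copies that share their reads. The entries that fell most in the deposited table were meu26 (−3.35), the pyridoxine importer gene bsu1 (−2.80), the thiazole synthesis gene thi2 (−2.21), pht1 itself, SPNCRNA.200 (−1.93), nmt1 (−1.91), SPBC460.04c (−1.81), SPNCRNA.389 (−1.74), the thiamine-repressible phosphatase gene pho4 (−1.74) and the amino acid permease gene SPCC794.03 (−1.73).

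Stress response genes rose in 18 of 24 cases with none lower in the pht1 deletion (list median 0.94, adjusted p = 1.33e-10, 19 adjusted over the list alone). Deposited folds were 2.38 for the metallothionein gene zym1, 2.27 for rds1, 1.80 for hsp16 and 1.32 for gst2. Subtelomeric genes rose in 46 and fell in 15 of 132 cases (list median 0.26, adjusted p = 2.25e-09, 67 adjusted over the list alone). Among them cmt2 (1.57), SPAC5H10.04 (1.53) and the nitric oxide dioxygenase gene yhb1 (1.52) rose, while SPBPB10D8.02c fell by 1.30 in the authors' table. Galactose and hexose genes rose in 7 of 14 cases (list median 0.53, adjusted p = 0.00686, 8 adjusted over the list alone), including mel1 (1.62), ght3 (1.53), gld1 (1.49) and fbp1 (1.05). Chaperone genes rose in 8 of 18 cases (list median 0.30, adjusted p = 0.00705, 9 adjusted over the list alone), including hsp16, ssa1 (1.18), hsp104 (0.81) and ssa2 (0.67) in the deposited table. Meiosis and sporulation genes rose in 30 of 134 cases with 12 lower (list median 0.11, adjusted p = 0.0194, 50 adjusted over the list alone). Among these are mug14 (2.04), meu27 (1.91), mug147 (1.49) and mug108 (1.48). With members called at an adjusted p under 0.01 these last lists were no longer called (adjusted p = 0.0737 for chaperones, 0.102 for meiosis and sporulation), and without members that share reads or overlap the second had an adjusted p of 0.0806. Annotated noncoding RNAs rose in 160 and fell in 19 of 658 cases (list median 0.39, adjusted p = 2.77e-14, 183 adjusted over the list alone). In the authors' table they include SPNCRNA.1133 (2.15), SPNCRNA.867 (1.72), SPNCRNA.679 (1.63) and SPNCRNA.1038 (1.59).

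Thiamine genes fell in 6 of 7 cases in the pht1 deletion (list median −1.74, adjusted p = 7.89e-05, 7 adjusted over the list alone). In the deposited table thi4 (−1.20) and thi9 (−1.15) join bsu1, thi2, nmt1 and pho4. Phosphate genes fell in 4 of 7 cases and 1 rose (list median −0.39, adjusted p = 0.0191, 5 adjusted over the list alone). The gene pho4 belongs to both lists, the acid phosphatase gene pho1 had −1.02, gde1 −0.46, pho84 −0.39 and tgp1 1.04. Ribosomal protein genes fell in 21 of 141 cases, a share not called (list median −0.12, adjusted p = 0.435, 17 adjusted over the list alone), and none rose, fewer than in other genes (adjusted p = 1.48e-08 for higher). Their list median lay at percentile 0.04 among random lists of the same size. Authors' folds were −0.78 for rps1201, −0.67 for rpp203, −0.66 for the RNase MRP gene rpp21 and −0.57 for rps2302.

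Apart from the Tf2 elements, the remaining lists were not called in the pht1 deletion by either direction of the list test. Among random lists of the same size, the medians of heterochromatin and RNAi (percentile 0.15), wtf (99.69) and MBF genes (97.6) lay near an end. Those of the other lists given below for this strain lay between percentiles 5.16 and 95.85. Heterochromatin and RNAi genes fell in 7 of 28 cases with none higher (lower, adjusted p = 0.109, 7 adjusted over the list alone). The lower ones include the RNAi genes rdp1 (−0.84) and dcr1 (−0.44) and the methyltransferase gene clr4 (−0.48). The SWR1 complex had 4 lower and 1 higher of 14 (adjusted p = 0.194, 5 adjusted over the list alone). In the deposited table alp5 was at −0.65, bdf1 at −0.54, swc5 at −0.54 and swc2 at 0.50. Histone genes had 2 higher and 2 lower of 11, with pht1 and hta1 (−0.60) lower (adjusted p = 0.645, 5 adjusted over the list alone). Ribosome biogenesis had 3 higher, including imp4 (0.53) and imp3 (0.35), and 2 lower of 41 (adjusted p = 0.628, 1 adjusted over the list alone). RNA surveillance had 3 lower of 25, including mtl1 (−0.41) and dis3 (−0.30) (adjusted p = 0.92, 2 adjusted over the list alone). Among MBF genes 3 of 17 rose, including cdt2 at 1.03 (adjusted p = 0.75, 2 adjusted over the list alone). Among cell separation genes 5 rose and 1 fell of 17, including adg2 at 0.84 and adg1 at 0.81 (adjusted p = 0.204, 7 adjusted over the list alone). The wtf family had 4 higher and 1 lower of 25 (adjusted p = 0.92, 5 adjusted over the list alone), with wtf18 and wtf23 both at 0.67 by the authors' values. Nitrogen starvation genes had 4 higher and 3 lower of 15, with isp6 at 1.04 and isp5 at 0.87 (adjusted p = 0.355, 7 adjusted over the list alone). Iron genes had 1 higher and 2 lower of 20, with frp2 at 0.84 and the ferroxidase gene fio1 at −0.52 (adjusted p = 0.75, 2 adjusted over the list alone). Of 8 M genes mam4 fell by 0.48 (adjusted p = 0.813, 1 adjusted over the list alone), and none of the 4 P genes passed (adjusted p = 1, 0 adjusted over the list alone). The gene ade6 fell by 0.35 while leu1 was at −0.35 without passing (adjusted p = 0.503, 2 adjusted over the list alone). SPMIT.10 alone of the 4 entries of the mitochondrial list fell, by 0.45 (adjusted p = 0.645, 1 adjusted over the list alone).

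In the double deletion, also labelled h− unlike wild type, the stress response was higher still and ribosome production lower. By the deposited adjusted p-value 1755 sense entries rose and 1973 fell, 869 and 293 of them by at least 2-fold. SPNCRNA.1054 (6.94), SPAC869.09 (6.39), SPAC186.02c (6.34), ddr48 (6.24), SPAC11D3.01c (5.93), SPBPB21E7.10 (5.92), SPNCRNA.540 (5.92), hsp3102 (5.81), SPNCRNA.549 (5.79) and prl65 (5.79) had the highest folds in the authors' table. The predicted transporter gene SPBC460.05 fell most (−3.85), followed by SPBPB2B2.08 (−3.25), the centromeric noncoding RNA SPNCRNA.485 (−2.90), whose reads are shared with copies, SPBPB10D8.01 (−2.80), the glutamine synthetase gene gln1 (−2.66), SPNCRNA.1124 (−2.64), SPBC460.04c (−2.62), SPAC8E11.10 (−2.53), SPBC23G7.13c (−2.51) and bsu1 (−2.46) in the deposited table.

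Stress response genes rose in 22 of 24 cases and fell in 2 in the double deletion (list median 2.87, adjusted p = 4.04e-09, 24 adjusted over the list alone). Authors' folds were 5.63 for zym1, 5.45 for rds1, 5.15 for hsp16, 3.83 for ctt1, 3.52 for gst2 and 3.40 for ish1. Chaperone genes rose in 15 of 18 cases and fell in 1 (list median 1.34, adjusted p = 2.35e-05, 17 adjusted over the list alone). Members include ssa1 (3.19), ssa2 (2.69) and hsp104 (2.65). Galactose and hexose genes rose in 11 of 14 cases (list median 1.80, adjusted p = 8.66e-04, 11 adjusted over the list alone). They include mel1 (5.28), gld1 (4.06), ght3 (3.66) and fbp1 (3.35) in the deposited table. The wtf family rose in 23 of 25 cases (list median 1.20, adjusted p = 1.55e-09, 23 adjusted over the list alone), with wtf6 at 1.78 and wtf18 at 1.67. Subtelomeric genes rose in 62 and fell in 37 of 132 cases (list median 0.37, adjusted p = 2.56e-04, 99 adjusted over the list alone). Higher ones include mug14 (4.79) and the predicted water channel gene SPAC977.17 (3.37). Noncoding RNAs rose in 351 and fell in 37 of 658 cases (list median 0.79, adjusted p = 3.45e-37, 385 adjusted over the list alone). Authors' folds were 5.29 for SPNCRNA.31, 4.65 for SPNCRNA.867, 4.01 for SPNCRNA.570 and 3.53 for SPNCRNA.133. Meiosis and sporulation genes rose in 57 and fell in 19 of 134 cases (adjusted p = 0.00835, 76 adjusted over the list alone), including mug147 (4.13), mug108 (3.59) and mug168 (2.03). M genes rose in 7 of 8 cases while mam4 fell by 0.97 (adjusted p = 0.00407, 8 adjusted over the list alone). MBF genes rose in 10 and fell in 2 of 17 cases, with mik1 at 1.16 (adjusted p = 0.0314, 12 adjusted over the list alone). With members called at an adjusted p under 0.01, the meiosis list had an adjusted p of 0.0936 and the M list one of 0.333.

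Ribosomal protein genes fell in 124 of 141 cases in the double deletion and 1 rose (list median −0.57, adjusted p = 2.0e-39, 126 adjusted over the list alone). They include rpp203 (−1.42), rps1201 (−1.34), the RNase MRP gene rpp21 (−1.24) that the list rule took in, and rps2302 (−1.10) in the authors' table. Ribosome biogenesis genes fell in 38 of 41 cases (list median −0.83, adjusted p = 5.51e-14, 40 adjusted over the list alone), with dbp3 at −2.04, dbp2 at −1.47, rpf2 at −1.27 and noc1 at −1.06. RNA surveillance genes fell in 19 of 25 cases (list median −0.59, adjusted p = 9.69e-05, 19 adjusted over the list alone). The list includes the exosome genes rrp41 (−0.99) and dis3 (−0.72) and mmi1 (−1.03) in the deposited table. Thiamine genes fell in 6 of 7 cases (list median −1.32, adjusted p = 0.0176, 6 adjusted over the list alone), including bsu1, pho4 (−2.14), thi2 (−1.53) and thi4 (−1.32).

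Apart from the Tf2 elements, the other lists changed in members but had no larger share of higher or of lower genes in the double deletion by the list test. Among random lists of the same size their medians lay between percentiles 7.94 and 89.6. Cell separation genes had 8 higher and 1 lower of 17 (higher, adjusted p = 0.277, 8 adjusted over the list alone) and fewer lower than other genes (lower, adjusted p = 0.0208), with adg2 at 1.76 and eng1 at 1.62 by the authors' values. Nitrogen starvation genes had 7 higher and 4 lower of 15 (adjusted p = 0.377, 11 adjusted over the list alone), including isp6 (2.95), ste11 (2.48), amt3 (1.76) and amt1 (−1.68). Iron genes had 8 higher and 5 lower of 20 (adjusted p = 0.456, 13 adjusted over the list alone), including shu1 (3.05), frp2 (1.43) and fio1 (−1.11). Histones had 4 higher and 4 lower of 11 (adjusted p = 0.872, 8 adjusted over the list alone), including hhf3 (1.18) and hht3 (1.14) in the deposited table. The SWR1 complex had 5 higher and 5 lower of 14 (adjusted p = 0.882, 10 adjusted over the list alone), including msc1 (0.86), swc5 (−1.14) and alp5 (−1.09). Heterochromatin and RNAi genes had 3 higher and 6 lower of 28, fewer higher than other genes (adjusted p = 0.0415, 8 adjusted over the list alone), with mst2 at 0.57 and clr3 at −0.49. Phosphate genes had 2 higher and 3 lower of 7, with pho1 at −0.89 and tgp1 at 1.03 (lower, adjusted p = 0.837, 5 adjusted over the list alone). The P gene map1 rose by 1.02 while the remaining 3 did not pass (adjusted p = 1, 1 adjusted over the list alone). The markers leu1 (−0.66) and ade6 (−0.65) fell (adjusted p = 0.195, 2 adjusted over the list alone). Of 4 entries of the mitochondrial list SPMIT.11 rose by 0.71 while SPMIT.10 (−0.41) and the nuclear gene rps3 (−0.39) fell in the authors' table (adjusted p = 0.752, 3 adjusted over the list alone).

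**Figure D1:**
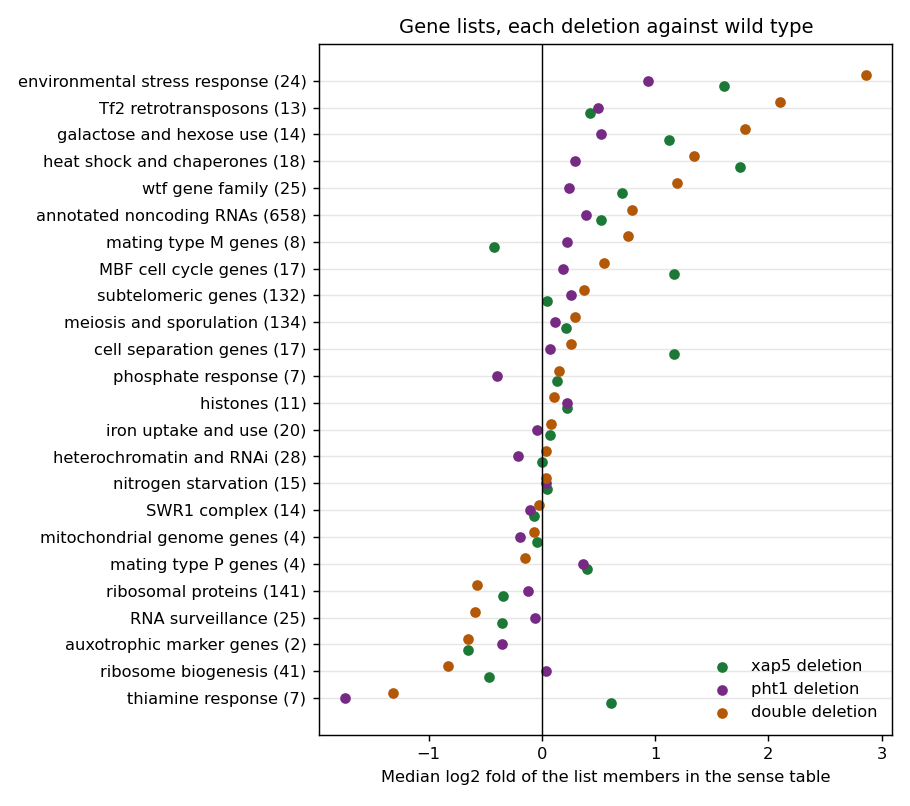
Median log2 fold against wild type (horizontal axis) of the members of each gene list in the sense table, for the xap5, pht1 and double deletion (points), with the number of members in brackets. The stress response list runs from 0.94 in the pht1 deletion over 1.61 in the xap5 deletion to 2.87 in the double deletion, and the ribosome biogenesis list lies at −0.83 in the double deletion.

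Antisense signal rose far more often than it fell in each deletion. Of 1052 listed loci with signal antisense to an annotated gene, the authors' adjusted p-values call 237 higher and 8 lower in the xap5 deletion, 436 higher and 50 lower in the pht1 deletion and 806 higher and 107 lower in the double deletion, with class medians of 0.70, 0.93 and 1.53. The table appears preselected for change, so these shares cannot be taken for all genes. At an adjusted p under 0.01, which 1530 of the 1561 entries reach in at least 1 comparison, 158, 332 and 771 loci were higher and 4, 35 and 100 lower. The 414 annotated antisense RNAs listed beside them had deposited medians of 0.74, 0.67 and 1.26, with 230, 199 and 335 higher and 16, 6 and 39 lower.

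In the xap5 deletion the largest antisense rise lay at hsp3102 (7.05), followed by the cell surface glycoprotein gene pfl8 (4.64), mug20 (4.44), the antisense RNA SPNCRNA.1075 (4.37), SPCC1020.13c (4.21) beside the deleted gene and SPBPB21E7.11 (3.40) in the authors' table. Signal fell at SPBC23G7.10c (−2.29), SPNCRNA.769 (−1.58), sap1 (−1.57), SPNCRNA.1487 (−1.46), SPNCRNA.742 (−1.39) and ssa1 (−1.32). The pht1 deletion had its highest deposited folds at ost3 (4.32), pfl8 (4.13), the amino acid transporter gene SPBC1652.02 (4.13), prl15 (3.92), SPAC212.06c (3.65) and the pyruvate decarboxylase gene pdc102 (3.56). Its lowest were at SPBPB2B2.06c (−4.86), the snoRNP gene nhp2 (−4.65), rps1001 (−4.56), the elongation factor gene tef103 (−3.54), rps601 (−3.50) and SPNCRNA.1376 (−3.42), which lies within the span of tef103. In the double deletion pfl8 (5.71), SPAC343.20 (5.56), SPCC191.10 (5.51), duc1 (5.47), SPNCRNA.1075 (5.30) and SPBC1685.04 (5.22) had the highest authors' folds, and ypt71 (−5.14), lsm5 (−4.98), rpl802 (−3.73), tif313 (−3.57), rpc11 (−3.41) and prp43 (−3.34) the lowest. Of 13 listed ribosomal protein loci, none passed in the xap5 deletion (median −0.30), 10 fell in the pht1 deletion (median −2.39) and 12 fell while 1 rose in the double deletion (median −2.83), with median sense folds of −0.32, −0.07 and −0.54 at these genes.

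**Figure D2:**
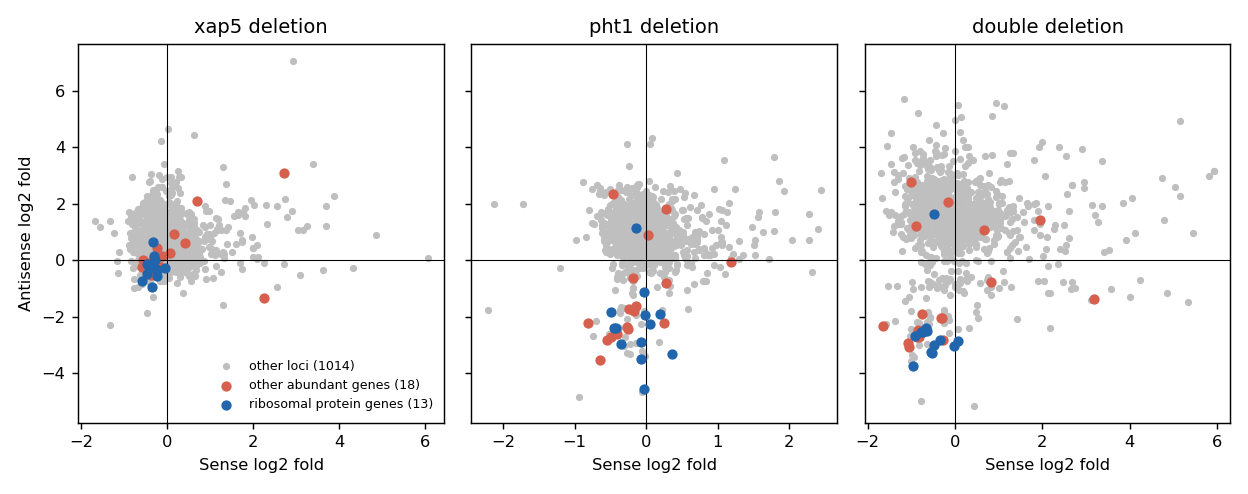
Deposited antisense log2 fold (vertical axis) against sense log2 fold (horizontal axis) of each gene listed in both tables, in the xap5, pht1 and double deletion, with 13 ribosomal protein genes and 18 other abundant genes marked. Most listed loci, which appear preselected for change, lie above 0 on the antisense axis, while the 13 listed ribosomal protein loci have medians of −2.39 and −2.83 in the pht1 and double deletion.

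Transcripts of LTRs and of the Tf2 retrotransposons were higher in all 3 deletions, most of all in the double deletion. The authors' table calls 21 of 117 LTRs higher in the xap5 deletion, 28 in the pht1 deletion and 79 in the double deletion, with 0, 0 and 1 lower, and the medians were 0.72, 0.79 and 1.81. LTRs noted as Tf2 had a median of 1.98 in the double deletion (71 LTRs) and those noted as Tf1 one of 0.98 (38 LTRs). In the xap5 deletion these medians were 0.72 for Tf2 and 0.82 for Tf1, and in the pht1 deletion 0.83 and 0.65. The highest deposited folds were 3.65, 3.33 and 3.05 for LTRs at I 4525577, I 4528282 and I 4528614 and 2.15 for II 4414197 to 4414489 in the xap5 deletion. All windows of those on chromosome I recur elsewhere, and these LTRs were not called in the double deletion (deposited adjusted p = 0.113, 0.311 and 0.0996). For the pht1 deletion the highest folds were 2.83 for II 93517 to 93860, 2.50 for I 3190954, 2.15 for III 1466447 and 1.92 for III 114382 in the authors' table. The double deletion had 5.17 for III 702136 to 702501, 4.79 for II 93517, 3.17 for II 4414197 and 2.97 for III 782301. An LTR at III 1894223 to 1894553 fell by 1.81 in the double deletion. Full Tf2 elements rose in 12 of 13 cases in the xap5 deletion (median 0.42, adjusted p = 4.71e-07, 13 adjusted over the list alone). All 13 rose in the pht1 deletion (median 0.49, adjusted p = 7.15e-11, 13 adjusted over the list alone) and the double deletion (median 2.11, adjusted p = 1.04e-06, 13 adjusted over the list alone). Deposited double deletion folds were 2.17 for Tf2-7, 2.15 for Tf2-1 and 2.11 for Tf2-9. The Tf2 elements are near-identical copies that share their reads, so that their folds are close to 1 measurement. The 49 LTRs without any recurring window had medians of 0.74, 0.67 and 1.15, with 8, 5 and 25 higher and none lower, and leaving out the 65 LTRs with over 10 percent recurring windows lowered the calls to 9, 6 and 28.

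**Figure D3:**
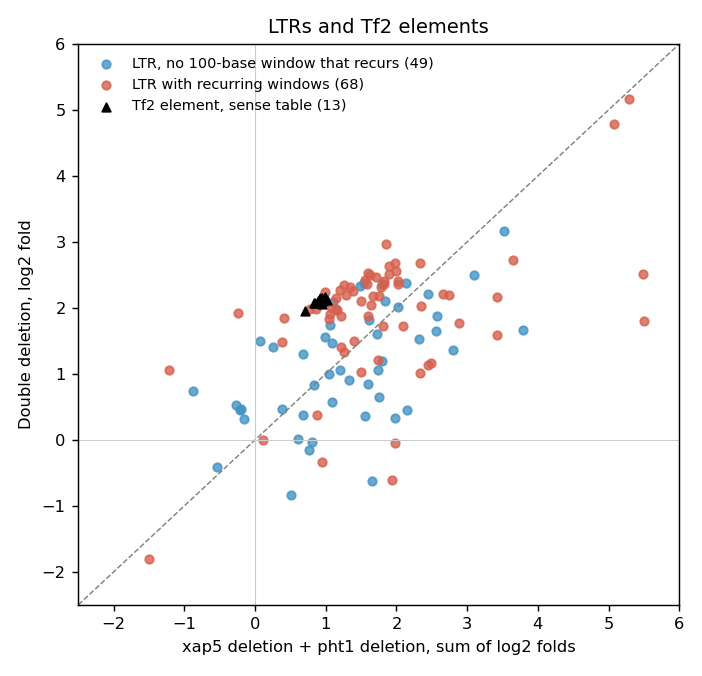
Log2 fold of each LTR and each Tf2 element in the double deletion (vertical axis) against the sum of its log2 folds in the xap5 and pht1 deletions (horizontal axis), with the dashed line where both are equal. The 13 Tf2 elements lie near 2.11 in the double deletion while their single folds have medians of 0.42 and 0.49.

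Intergenic regions changed in the same direction in smaller shares. By the authors' calls 162 of 6121 regions rose and 42 fell in the xap5 deletion, 101 rose and 12 fell in the pht1 deletion and 917 rose and 100 fell in the double deletion, with medians of 0.10, 0.22 and 0.43. In the xap5 deletion the regions I 82346 to 82745 (5.11), III 2057070 to 2057083 (4.53), I 4461223 to 4461696 (4.23) and II 3938708 to 3939226 (4.08) had the highest deposited folds, and III 2057070 lies within the reference span of ssa2. Next to the stretch inside xap5, the regions II 2122818 to 2123086 (−3.93), which adjoins SPBC23G7.13c, II 2133395 to 2134980 (−3.74), which adjoins mat3-Mc, and I 2913021 to 2913062 (−2.75), within the reference span of mfm2, fell most. For the pht1 deletion the authors' folds were highest at I 311713 to 311919 (6.86), II 3421370 to 3421416 (6.58), I 82346 (3.74) and, with an adjusted p of 1.33e-05, the region II 4524971 to 4526224, which shares reads with copies. They were lowest at II 3225985 (−3.09), III 1167324 (−3.02), II 4476675 (−2.03) and II 3941700 to 3941983 (−1.96), which adjoins thi2. For the double deletion I 5496598 to 5496843 (6.61), which adjoins SPAC869.09, I 311713 (5.64), II 948224 to 948887 (5.58) and I 82346 (5.27) were highest in the deposited table. Lowest were I 792275 (−3.83), I 786400 (−3.68), II 546792 (−3.30) and II 85632 to 87726 (−3.09). Regions were short, 2961 of them under 100 bases, and many adjoin an annotated gene, so their folds are not independent of the genes beside them.

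**Figure D4:**
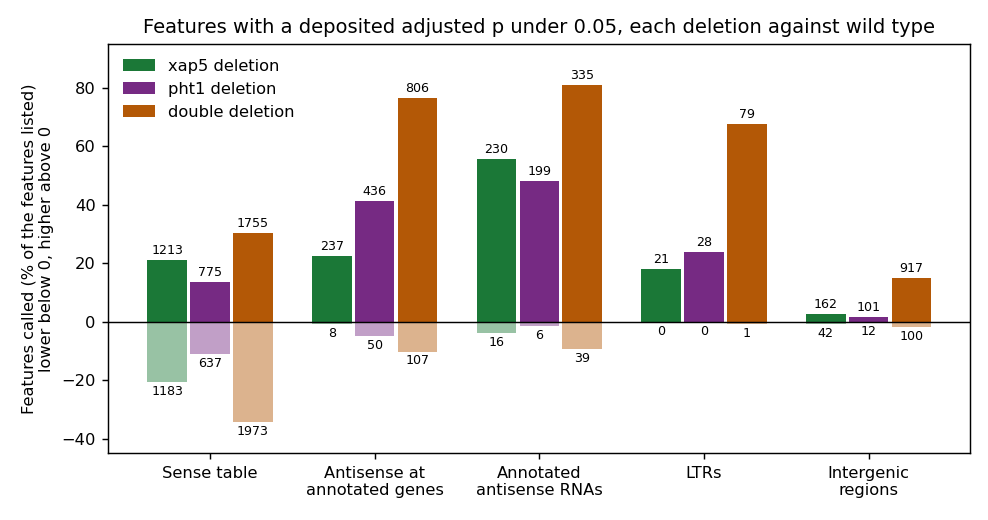
Share of the listed features of each class (vertical axis, percent) with a deposited adjusted p-value under 0.05, higher above 0 and lower below 0, for the xap5, pht1 and double deletion (bars, with counts). LTRs, intergenic regions and antisense entries are called higher more often than lower, while the sense table has 1755 higher and 1973 lower in the double deletion, and the antisense entries appear preselected for change.

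The double deletion was set against each single deletion by differences of the authors' folds, which carry no error and were not tested. Tf2 elements stood out: their double deletion fold lay above both single folds in 13 of 13 cases, and the interaction, the double fold minus both single folds, had a median of 1.21. These copies share their reads, so that the 13 cases are close to 1 measurement, and 68 of the 117 LTRs hold recurring windows too. Among LTRs the double deletion fold lay above both single folds in 83 of 117 cases, and of 79 called higher in the double deletion 41 were called in neither single deletion, with a median interaction of 0.24. For antisense signal at annotated genes these numbers were 686 of 1052, 365 of 806 and −0.18, and for intergenic regions 3217 of 6121, 736 of 917 and 0.11. For sense entries they were 2037 of 5744, 521 of 1752 and −0.03. The antisense loci appear chosen for a change, and 871 of the 1052 pass at an adjusted p under 0.01 in the double deletion. Their counts are therefore set in part by that choice. Stress response genes had a median difference of 1.19 from the xap5 deletion and 2.10 from the pht1 deletion, with a median interaction of 0.11. Chaperone, MBF and cell separation genes were on the whole lower in the double deletion than in the xap5 deletion, with median differences of −0.36, −0.49 and −0.60, and had median interactions of −0.65, −0.85 and −0.69. Thiamine genes had a median difference of −2.27 from the xap5 deletion and 0.15 from the pht1 deletion, and bsu1 had −2.46 in the double deletion beside −2.80 in the pht1 deletion. The fold of nmt1 in the double deletion, −0.30 (adjusted p = 0.455), lay between −1.91 in the pht1 deletion and 2.52 in the xap5 deletion.

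Single features with a large difference came from several of these groups. Against the xap5 deletion the double deletion folds in the authors' table were higher by 5.97 for SPMTR.04, 5.21 for mat3-Mc, 5.11 for mat1-Mc, 5.03 for SPAC977.05c and 4.81 for SPAC212.10. The difference was −3.43 for mfc1, −3.15 for SPNCRNA.1124, −3.12 for bsu1, −2.92 for agp3 and −2.83 for nmt1. Against the pht1 deletion it was 4.26 for SPAC869.09, 4.16 for meu26, 3.95 for SPNCRNA.540, 3.95 for prl65 and 3.88 for hsp3102. It was −2.45 for xap5, −2.44 for SPAC212.08c, −2.39 for SPCC191.04c, −2.18 for SPNCRNA.485 and −2.14 for SPBC460.05. The interaction was highest for SPAC513.04 (6.42), SPMTR.04 (5.70), mat3-Mc (5.05), mat1-Mc (4.94) and SPNCRNA.200 (4.64). The xap5 deletion is labelled h+ and the double deletion h−, so differences between them cannot be told apart from mating type. The mat1-Mc, mat3-Mc and SPMTR.04 entries did not follow the labels, so their interaction may hold a mating-type difference too. The interaction was lowest for mfc1 (−5.22), agp3 (−3.91), SPAC186.08c (−3.39), SPCC191.04c (−3.39) and SPNCRNA.911 (−3.27) from the deposited folds. Among antisense entries it was highest for SPBPB2B2.06c, followed by nhp2 (3.19), ppr6 (3.04), nse5 (2.99) and SPAC26F1.11 (2.93). The lowest values were those of hsp3102 (−6.49), ost3 (−4.59), lto1 (−3.83), SPBC1652.02 (−3.31) and SPNCRNA.676 (−3.11). Counting features called in an entering comparison with a difference of at least 1, the deposited folds gave 697 sense entries against the pht1 deletion, 431 against the xap5 deletion and 263 for the interaction. The same counts were 641, 600 and 434 antisense entries, 56, 60 and 20 LTRs and 536, 455 and 292 intergenic regions.

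The comparisons shared more changed sense genes than independent lists would. The authors' calls of the xap5 and pht1 deletions shared 477 higher genes where independent lists give 164 and 276 lower ones where they give 131, and 60 genes went in opposite directions, among them nmt1, thi2 and bsu1. The xap5 and double deletions shared 1040 higher and 1051 lower genes (370 and 406 for independent lists) with 31 opposite, and the pht1 and double deletions 631 and 480 (237 and 219) with 51 opposite. All 3 comparisons use the same wild type libraries, and the 0 calls shared by simulated strains without change do not show what these libraries add to the calls shared here. Across 5093 genes, which are not independent replicates, Pearson's r of the deposited folds was 0.61 between the single deletions, 0.82 between the xap5 and double deletion and 0.77 between the pht1 and double deletion, where shared wild type libraries alone gave 0.43 in simulation. Genes with a very high p-value or a fold from a group without reads in any comparison were left out. Simulated folds were not filtered in that way, so observed and simulated values are not fully alike. The covariances were 0.227, 0.655 and 0.415 against a simulated 0.0183, 0.0182 and 0.0182. Part of the excess may still come from the shared wild type libraries, which could not be split. For antisense signal at annotated genes at an adjusted p under 0.01, the single deletions shared 42 higher loci, the xap5 and double deletions 128 and the pht1 and double deletions 191. No number for independent lists is set beside these, because it depends on how many loci were tested before the table was drawn up.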

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

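Added after the data were seen were the settings with only antisense at annotated genes, with regions of at least 100 bases, with list members and differences called at an adjusted p under 0.01, with a background of protein-coding genes, and, for class medians, lists and differences, those without features that share reads or overlap. No paired analysis was possible because the deposited tables hold no value per library. For that reason the planned DESeq2 size factors and test, low-count filters, class-specific library sizes, fits of 2 groups, leave-one-out fits, read sums per class, camera and fry and an expression-matched background were not run either. A planned check at low expression was not run, and what depth limits remains open.

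Of 111 alternative values 78 lay within a ratio of 1.5 (counts) or 0.1 (medians) of the main value, 33 moved further and 0 reversed. Only medians with a main value beyond 0.1 in either direction could reverse, and counts could not. Adjusting the p-values again within each table left 12 of 12 within these limits. For LTRs and intergenic regions this changes nothing by construction, because the deposited values are already adjusted over the table. Antisense calls rose from 540, 724 and 1347 to 691, 857 and 1385 in the xap5, pht1 and double deletions. That table appears preselected for change, so adjustment within it has no clear meaning. At an adjusted p under 0.01, fewer features pass by construction: 825 sense entries in the pht1 deletion, 3 and 6 LTRs in the xap5 and pht1 deletions, and 105, 48 and 590 intergenic regions in the xap5, pht1 and double deletions, with 174 for the intergenic interaction. Shared sense genes were then 301 higher and 118 lower for the single deletions and 419 higher and 239 lower for the pht1 and double deletions. With a change of at least 2-fold as well, 533, 266 and 1162 sense entries and, in the single deletions, 12 and 16 LTRs remained. Shared genes were 143 higher and 11 lower for the single deletions, 400 and 41 for xap5 and double, and 214 and 24 for pht1 and double. Without features that share reads or overlap, LTR calls were 9, 6 and 28, LTR differences 14 (against pht1), 14 (against xap5) and 4 (interaction), LTR medians 0.67 and 1.174 in the pht1 and double deletion, and antisense calls in the pht1 deletion 469. The counts have fewer features by construction, and for the medians the cause was not tested. With only antisense at annotated genes the xap5 deletion had 245 calls, fewer by construction of the smaller table, and the pht1 deletion a median of 0.93, where the cause was not tested. Of 34 list calls, 30 held with members called at 0.01, 31 against protein-coding genes and 29 without features that share reads or overlap. By construction, the second setting removes nearly all of the noncoding RNA list and the third all Tf2 elements, so their calls in all 3 comparisons are lost there.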

Other observations

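Chosen only after the results were seen were the look at pseudogenes and small nucleolar RNAs, the tests of explanations for the mating type genes (not the list tests, which were fixed earlier), both tests on antisense signal at ribosomal protein genes, the test of scaling on LTRs and the test of sense folds at loci with higher antisense. Predictions for the tests of shared reads and of neighbours at LTRs, of convergent genes and of introns were written before those values were computed, but after the tables had arrived.

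Pseudogenes rose more often than they fell, and no list test was run on them. Of 27 pseudogenes with sense folds, 14, 9 and 20 rose and 1, 0 and 3 fell in the xap5, pht1 and double deletions, with median deposited folds of 0.68, 0.40 and 1.31. Of 7 small nucleolar RNAs 2, 0 and 1 rose and 1, 0 and 0 fell, with medians of 0.20, −0.14 and −0.11.

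The entries mat1-Mc, mat3-Mc and SPMTR.04, which share their reads, had a median deposited fold of −4.28 in the xap5 deletion and were not lower in the other strains, while mam4 fell in all 3. That value argues against equal M-specific RNA in wild type and xap5 deletion, which the shared label h+ would give. The same entries had a median of 0.16 in the pht1 deletion, labelled h−, although the labels of that strain and wild type differ. The wild type libraries may thus depart from their label as well, which was not tested. Loss of xap5 whatever the pht1 genotype is argued against by the median of 0.93 in the double deletion, provided that strain lacks xap5 as labelled (its xap5 entry had −2.11, a stretch inside the gene −0.09). The double deletion is also labelled h−, unlike wild type and the xap5 deletion, so its mating type could hide such an effect. Another mating-type cassette in the xap5 deletion libraries would raise P genes, and the highest, map1, had 1.28 there but also 1.02 in the double deletion, so this remains open, with no entry for a P cassette in the table. An effect of xap5 loss that needs pht1 was not tested and stays open too, and in the mating type region 3 of 7 intergenic regions fell and 1 rose in the xap5 deletion (median −0.84), 0 fell and 1 rose in the pht1 deletion (median 0.10), and 1 fell and 1 rose in the double deletion (median 0.47).

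Antisense signal fell at most of the 13 listed ribosomal protein loci in the strains lacking pht1 (medians −2.39 and −2.83) but at none in the xap5 deletion (median −0.30). Listed loci appear chosen for a change, so the counts, medians and contrasts given here are set in part by that choice. They do not stand for all ribosomal protein genes or all abundant genes. Antisense signal at the 13 loci did not follow the sense transcript, since the median difference of antisense and sense fold was −2.48 in the double deletion. If reads of abundant sense transcripts were counted on the wrong strand, in a lower share in the deletion libraries, other abundant genes should fall too. Their median was −2.04 in the double deletion (18 loci, 12 lower and 3 higher), −1.78 in the pht1 deletion and −0.08 in the xap5 deletion (1 lower and 2 higher), with double deletion folds of −3.07 at gpm1, −2.92 at eno101 and −1.92 at tdh1. At ssa1 antisense signal fell by 1.35 while its sense transcript rose by 3.19, and at adh1 (2.78) and met6 (2.05) antisense signal rose. Wrong-strand reads therefore remain a candidate, a true loss of antisense RNA at highly expressed genes predicts the same, and the tables cannot tell them apart; the median was 1.56 at the 1014 other loci.

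LTR signal in the double deletion could come from shared reads, neighbours or scaling. LTRs without a recurring window had a median of 1.15 (quartiles 0.46 and 1.75, 25 of 49 higher). Those over 1000 bases from any sense entry called higher had 1.45 (22 of 40 higher). These values argue against shared reads alone and against sense neighbours alone. Annotated antisense RNAs, of which 335 rose in this strain, and intergenic regions were not counted as neighbours, so run-in from them was not tested. Intergenic regions had a median of 0.43, which argues against a scaling that raised all features alike. Under both filters together 17 LTRs remained, with a median of 0.84 (quartiles 0.38 and 1.41, 6 higher), under the bound of 1 that each test used. How much of the rise is the LTRs' own transcription stays open.

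Further hypotheses were tested on gene structure. For both tests on loci with higher antisense, these were protein-coding loci called at an adjusted p under 0.01. They numbered 153, 331 and 759 in the xap5, pht1 and double deletions. If antisense signal ran in from convergent neighbours, such loci should have a convergent gene within 500 bases more often. In the double deletion they had one less often (43.3 against 50.6 percent, odds ratio 0.748, Fisher exact p = 2.48e-04, adjusted p = 3.72e-04). That argues against it for the 759 loci as a set, but not for a part of them. In the xap5 deletion the odds ratio was 0.790 (Fisher exact p = 0.163). In the pht1 deletion it was 2.01 (65.3 against 48.4 percent, Fisher exact p = 2.58e-09, adjusted p = 7.74e-09), so read-through from convergent genes stays possible in that strain. The pht1 and double deletions shared 191 higher antisense loci at annotated genes, so it stays possible for a part of the double deletion loci too. Among protein-coding genes other than those of ribosomal proteins, the 2295 with introns had a lower median fold than the 2604 without in the xap5 deletion (difference −0.0638, permutation p = 1e-05, the smallest possible). That is less than the 0.1 set beforehand for the xap5 deletion, so no call is made there, and the difference was −0.06 in the pht1 deletion (permutation p = 1e-05). In the double deletion the difference was −0.14 (permutation p = 1e-05, 22.1 against 33.4 percent higher), which passes the same bounds, though they were not set for that strain. Sense folds at loci with higher antisense differed from those elsewhere by −0.042 in the double deletion (permutation p = 0.174), −0.04 in the xap5 deletion (permutation p = 0.321) and −0.09 in the pht1 deletion (permutation p = 4.0e-05, adjusted p = 1.2e-04, with 68 lower and 28 higher). The bounds for this test, written after the data were seen and for the double deletion, were a difference beyond −0.1 with p under 0.05. The double deletion meets neither, and in the pht1 deletion a small difference is present that stays within the size bound. Genes are not independent, and these p-values over genes are likely too small.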
